A study of Mus musculus with 6 samples.

How the data were processed

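Gene expression was measured by RNA sequencing of total RNA in 6 mouse libraries, 3 labelled JMML and 3 labelled WT. Libraries were made with a stranded total RNA kit that depletes ribosomal RNA, per the labels' protocols. The deposited values are raw counts per Ensembl gene, whole numbers with no normalization. Per the submitters' processing notes the genome build was GRCm38, and the tools named there are bcl2fastq 2.18.0.12, STAR 2.5.3a, Picard 2.0.1, StringTie 1.3.3b, R 3.5.0 and DESeq2 1.22.2, with no role or order. Which tool counted, the annotation release, the strand setting and the treatment of mates and multi-mapped reads are not given in the sources used here. Among counts of 1 to 20, between 51.6% and 58.8% were even in each library, so both mates of a pair appear to have been counted, and counts then overstate the number of independent fragments. Genes with near-identical copies, such as the globin pairs, and antisense neighbours are uncertain for the same reason.

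Each table held 46078 genes, and 45229 identifiers (98.2%) matched GENCODE vM21 for GRCm38, from which symbols, biotypes, positions and exon lengths were taken; 849 did not match. Their counts took between 0.142% and 0.167% of each library and stayed in the analysis. Groups and replicate numbers came from the labels. Totals ranged from 47096464 to 108395459 counts, and 1 count was worth 0.00951 to 0.0192 CPM. Counts of no library pair agreed within sampling noise (chi-square per degree of freedom of 115 or more), so none was a copy of another. All 6 were used as separate samples, which this check alone cannot establish.

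Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after filterByExpr by group and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 29.4%. Standard errors are the absolute log2 fold change divided by the square root of F. Lists of genes were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over 36 lists, and again with an estimated correlation and with fry. There were 37 lists with 581 symbols, fixed before the data were examined, and 3 symbols had no identifier in the tables. Camera compares the test statistics of list members with those of all other genes, so its direction can differ from the sign of the median or mean. Median and mean or test differed in sign for the fetal, dendritic, hepatocyte, MAPK, osteoblast, mitochondrial and sex-linked lists.

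Named genes followed a rule fixed in advance. It took the 12 largest increases and 12 largest decreases among called genes with a mean log2 CPM of 2 or more and no overlap between groups, leaving out sex-linked genes, antigen receptor segments and unnamed gene models. It added up to 4 members of each list with the smallest p, 12 genes of the Ras pathway and fetal program whatever their values, and the sex-linked genes; 171 genes resulted. Members outside this rule were chosen after their values were seen. Some genes that the rule names are not reported here.

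Counts were simulated from each gene's mean over all 6 libraries, with 200 genes changed in JMML. The test on 17708 genes recovered 2% of 50 genes changed 1.5-fold, 24% at 2-fold, 86% at 4-fold and 94% at 8-fold. Of 109 calls, 6 (5.5%) were false. In that setting changes under 2-fold were detected only in part. Only 200 genes changed there, against 4737 called in the data, which makes the adjusted threshold stricter. The rates therefore need not hold for the real comparison. In the same simulation camera called the 1 list that was doubled and 0 unmoved lists, but simulated genes vary independently, which real genes do not.

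The alternatives were DESeq2 size factors or library totals alone as scaling, DESeq2 1.42.0 and limma-voom as tests, no filter or a filter of 50 counts in 3 libraries, the replicate number as a block, the identifier letter as a covariate, only libraries with the letter M, each replicate left out in turn, and sets of genes left out. Added after the data were seen were thinning of all libraries to the smallest total and removal of the trend with exon length by a loess offset per library (span 0.5). The offset was run as fitted and, once those values were known, also centred in each library. Loci of the TEC and sense-intronic biotypes were classed by position against all other annotated genes. Intervals of medians are 95% bootstrap intervals from 10000 draws of list members or loci. These are not independent replicates, so the intervals do not measure the spread between libraries. Scripts used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.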

Results

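Total RNA from mice was sequenced in 2 groups of 3 libraries. One group is labelled JMML, for juvenile myelomonocytic leukemia, a blood cancer of early childhood marked by excess monocytic and granulocytic cells and often by activating changes in the Ras pathway. The other group is labelled WT. The series title places the samples in a mouse model of fetal blood formation and leukemia, and the comparison asks which transcripts differ between the leukemic and the control samples. The labels name neither the tissue, nor the age, nor the strain, nor the altered gene. Total counts were 91976512, 108395459 and 95382538 in JMML replicates 1, 2 and 3, and 61656272, 47096464 and 56163368 in WT replicates 1, 2 and 3, so the JMML libraries were deeper. The identifiers of JMML replicates 1 and 2 end in F, and those of the other 4 libraries end in M. The identifiers of JMML replicate 3 and WT replicate 3 share a prefix, whose meaning the labels do not give, so these 2 may be related or handled together. Xist, the X-inactivation transcript, had 54449 and 49961 counts in JMML replicates 1 and 2 and at most 36 in any other library, and the 4 Y-linked genes Eif2s3y, Uty, Ddx3y and Kdm5d had 0 counts in JMML replicates 1 and 2 and 1777 or more in each other library. These counts are those of female mice in JMML replicates 1 and 2 and of male mice in the other 4 libraries. The letters match them, so sex differs partly along with the group. All WT libraries carry M, so with the letter as a covariate the group difference rests on JMML replicate 3 against WT. The labels do not say that the replicates are separate animals, so p-values measure the spread between these 6 samples.

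Genes of B cells, platelets and red cells were far lower in JMML, and genes of antigen presentation and glycolysis and part of the myeloid granule genes were higher. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2245 of 18097 tested genes were higher in JMML and 2492 were lower, 4737 in total at an adjusted p under 0.05. Of these, 2491 differed by at least 2-fold, 725 higher and 1766 lower. The groups did not overlap in 47.5% of genes, against 10% by chance for 3 against 3. Among called genes with a mean log2 CPM of 2 or more and no overlap between groups, leaving out sex-linked genes, antigen receptor segments and unnamed gene models, the largest decreases were those of Pax5, the commitment factor of B cells (log2 fold change −6.76 ± 0.77 SE), Ppbp, a platelet chemokine (−6.59 ± 0.91), and Tubb1, the platelet tubulin (−6.15 ± 0.70). The largest increases in the same set were those of Sept3 (4.86 ± 0.32), Xcr1, a chemokine receptor of cross-presenting dendritic cells (4.51 ± 0.38), and the Toll-like receptor gene Tlr11 (4.17 ± 0.22). With library totals alone as the scaling, 27.0% of calls were higher in place of 47.4%, and the median of all genes shifted by −0.18 (log2). With the identifier letter as a covariate, 969 genes were higher and 1250 lower.

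Of 36 fixed gene lists with at least 3 tested members, camera with a preset correlation of 0.01 called 17, 10 higher and 7 lower. None of the 17 was called with an estimated correlation, and that adjusted p is given with each list below. Among the 10 splits of the 6 libraries into 3 and 3, another split called 20 lists, so the number of list calls at the preset correlation does not set the real grouping apart. With the rotation test fry the calls of the B-cell and erythroid lists (each at an adjusted p of 0.0572) and of the endothelial, mature neutrophil, interferon, cholesterol and histone lists ended, and the p53 and sex-linked lists were called. The counts of members below come from the test of single genes. Where a count moved by over 1.5 times and by at least 2 members in another setting, the other count follows; block means the replicate number as a block, letter the identifier letter as a covariate, and M only the 4 libraries with that letter. A called list for which no other median is given kept its median within 1.5 times of the main one in every setting, so fewer called members do not mean smaller changes there. A setting is named beside a called gene of the rule where it ended that gene's call or moved its log2 fold change by over 1.5 times.

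Genes of B cells and T cells were lower in JMML. All but 1 of 18 tested members of the B-cell list were lower in JMML (17 lower adjusted over the list alone), with a median log2 fold change of −4.38 and an adjusted p of 1.45e-07 in camera (adjusted p = 0.557 with an estimated correlation). The 17 lower became 7 with the letter and 6 in M only. Pax5, at chromosome 4, 44524757 to 44710487 (GRCm38), had 48.6 ± 41.4 CPM (normalized counts at a common library size; SD, n = 3) in WT and 0.446 ± 0.243 in JMML. Ebf1, another B-cell transcription factor, fell by 5.37 on the log2 scale, and Rag1, which cuts antigen receptor genes for recombination, fell by 5.51. Bach2, a repressor active in B cells, fell by 4.35. Of the plasma cell list, 3 of 9 tested members were lower and 1 was higher (4 and 1 adjusted over the list alone), without a call (adjusted p = 0.192 in camera). Jchain, which joins secreted antibodies, was lower (−3.53 ± 0.40), and Xbp1 was higher (0.72 ± 0.10). In the T-cell list, 15 of 17 members were lower (17 adjusted over the list alone; median −1.64, adjusted p = 4.46e-07 in camera and 0.557 with an estimated correlation). Cd2 and Cd3d, surface proteins of T cells, had fold changes of −2.10 ± 0.25 and −1.93 ± 0.30. The 15 lower became 8 with the block, 3 with the letter, 4 in M only, 9 without JMML replicate 2, 9 without WT replicate 1 and 6 without WT replicate 2. Cd3d lost its call with the letter (−1.73) and in M only (−1.70). Natural killer cell markers gave no call, with 1 of 11 lower (Ccl5, −1.03 ± 0.30) and 0 called in either direction adjusted over the list alone (median 0.07, between −0.24 and 0.63 over all settings, adjusted p = 0.714). The call of Ccl5 ended in 7 of 21 alternative settings, namely with the letter, after thinning to equal totals and without JMML replicate 1 or JMML replicate 3 or any single WT replicate. None was higher, against 2 with the DESeq2 Wald test, without the low-count filter and with the block, and 4 in M only and without JMML replicate 1. The list was called higher with the letter (median 0.60, adjusted p = 0.0337) and in M only (0.63, adjusted p = 0.0107).

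Platelet and red cell genes fell as well. In the megakaryocyte list, 14 of 15 members were lower (14 adjusted over the list alone; median −3.71, adjusted p = 6.94e-08 in camera and 0.557 with an estimated correlation). Gp1ba, part of the platelet receptor for von Willebrand factor, fell from 14.2 ± 7.46 to 0.566 ± 0.186 CPM, and Gp9 of the same receptor complex fell by 3.91 on the log2 scale. Ppbp lies at chromosome 5, 90768518 to 90770063, and had 169 ± 138 CPM in WT and 1.76 ± 1.28 in JMML. In the erythroid list, 15 of 19 members were lower (18 adjusted over the list alone; median −2.46, adjusted p = 6.76e-08 in camera and 0.557 with an estimated correlation). Slc4a1, the anion exchanger of the red cell membrane, had a fold change of −4.10 ± 1.06 and varied within JMML, at 4931, 291 and 756 counts in replicates 1, 2 and 3. Car1, a carbonic anhydrase, and Gata1, the erythroid transcription factor, had fold changes of −1.59 ± 0.33 and −1.53 ± 0.35. The 15 lower became 1 with the letter, 4 without JMML replicate 3, 3 without WT replicate 1, 3 without WT replicate 2 and 5 without WT replicate 3. In every other setting with these 19 members tested, 15 to 19 were lower, and over all settings the list median lay between −3.23 and −1.92, at −2.69 with the letter. Slc4a1 lost its call with the letter (−5.61) and without JMML replicate 3 (−3.68) or any single WT replicate, and was at −6.18 without JMML replicate 1. Car1 was at −2.45 with the letter and −2.41 in M only, and Gata1 lost its call with the letter (−1.49) and without WT replicate 1 (−1.36). The adult globin genes have near-identical copies, so counts of each copy are uncertain; together the haemoglobin genes took 0.0211 ± 0.0204% of counts in JMML and 0.180 ± 0.0528% in WT. Of the heme synthesis list, 9 of 13 members were lower and 1 was higher (12 and 1 adjusted over the list alone; median −1.09, adjusted p = 8.59e-05 in camera and 0.557 with an estimated correlation). Slc25a37, a mitochondrial iron importer of red cell precursors, fell by 1.64 on the log2 scale. The 9 lower became 1 with the letter and 5 without WT replicate 1.

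Stem cell and vessel genes fell in part. In the hematopoietic stem cell list, 14 of 21 members were lower and 2 were higher (14 and 2 adjusted over the list alone; median −1.24, adjusted p = 2.4e-05 in camera and 0.459 with an estimated correlation). Slamf1 (CD150) had a fold change of −4.45 ± 0.46 and Meis1 of −1.49 ± 0.19. The 2 higher members, named after their values were seen, were the progenitor receptor gene Flt3 (0.97 ± 0.18) and Ly6a (2.41 ± 0.65). The 14 lower became 8 with the letter and 8, 6 and 9 without WT replicates 1, 2 and 3. Of the endothelial and stromal list, 9 of 18 members were lower (11 lower and 1 higher adjusted over the list alone; median −1.19, adjusted p = 0.000919 in camera and 0.713 with an estimated correlation). Stab2, a scavenger receptor of sinusoidal endothelium, fell from 112 ± 26.0 to 7.23 ± 3.53 CPM, and Cxcl12, the chemokine that retains stem cells, fell by 3.37 on the log2 scale. The 9 lower became 5 with the block, 5 without JMML replicate 2, and 4 without WT replicate 2 or WT replicate 3, and without the latter 2 were higher. The median became −2.13 with the letter and −2.09 in M only.

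**Figure D1:**
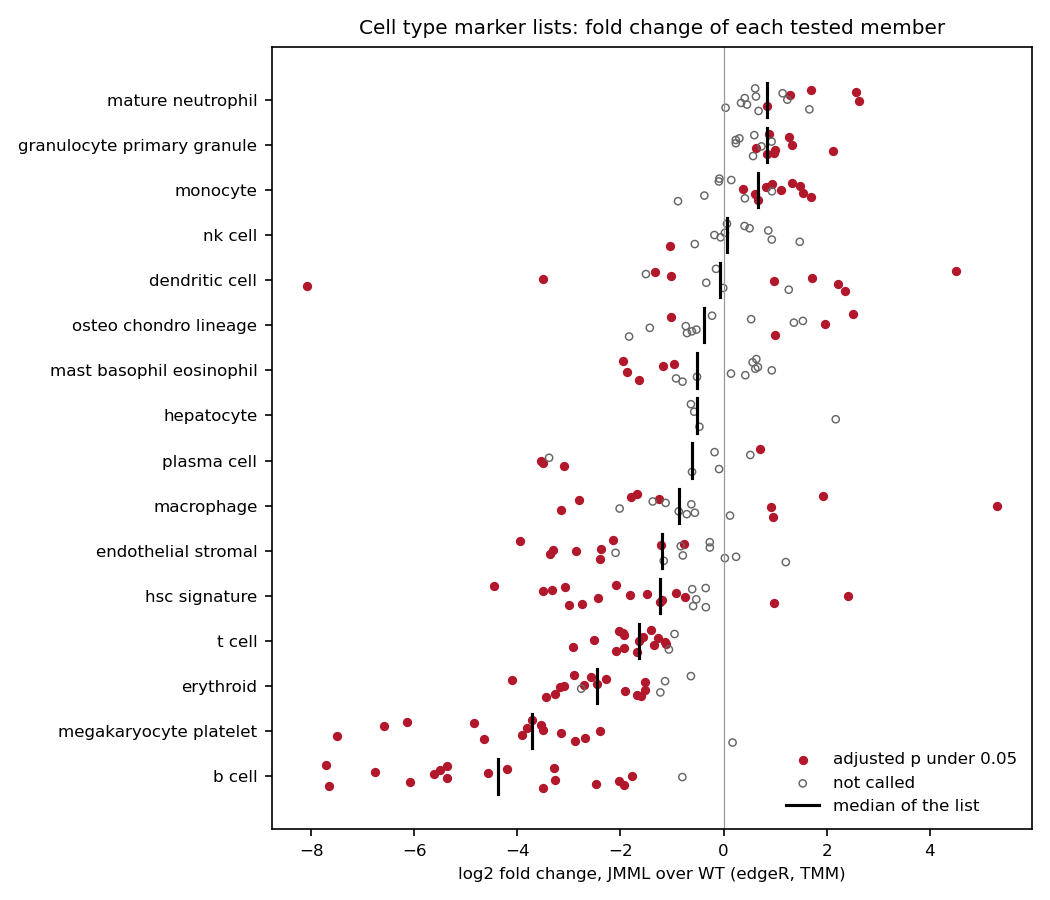
Log2 fold change (JMML over WT, x axis) of each tested member of the cell type lists (y axis); filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. The B-cell median is −4.38 and the megakaryocyte median −3.71, while the monocyte median is 0.67.

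Part of the primary granule, monocyte and neutrophil genes were higher in JMML. In the primary granule list, 8 of 15 members were higher (10 adjusted over the list alone; median 0.84, adjusted p = 5.21e-06 in camera and 0.399 with an estimated correlation). Ms4a3, a marker of granulocyte and monocyte progenitors, rose from 128 ± 8.07 to 307 ± 17.5 CPM, and Gstm1, a glutathione transferase, had a fold change of 1.33 ± 0.19. The 8 higher became 4 without WT replicate 2 and 5 with the gene length trend removed in both forms. In the monocyte list, 10 of 17 members were higher (10 adjusted over the list alone; median 0.67, adjusted p = 0.000457 in camera and 0.557 with an estimated correlation). Ly6c2 (1.48 ± 0.14) and F13a1, coagulation factor XIII of monocytes (1.55 ± 0.22), were among them. With the identifier letter as a covariate the monocyte call ended at an adjusted p of 0.0512, with a median of 0.40. The 10 higher became 5 with library totals alone, 6 with the block, 5 with the letter, 6 in M only, 6 without JMML replicate 2 and 5 without WT replicate 1 or WT replicate 2, and 2 were lower with the letter and in M only, where the median was 0.43. F13a1 was at 1.02 with the letter. In the mature neutrophil list, 5 of 15 members were higher (7 adjusted over the list alone; median 0.84, adjusted p = 0.00126 in camera and 0.589 with an estimated correlation), among them the collagenase gene Mmp8 (2.62 ± 0.43) and Trem1 (1.69 ± 0.28). The 5 higher became 8 without the low-count filter, 2 with the letter and in M only, 3 without JMML replicate 1 or JMML replicate 3, 2 without WT replicate 1 or WT replicate 2, and 2 and 3 with the length trend removed as fitted and centred. The median became 1.61 without WT replicate 3, and Mmp8 was at 1.69 with the letter and 1.73 in M only. Macrophage genes went both ways, with 4 of 17 higher and 5 lower (4 and 5 adjusted over the list alone; median −0.87, adjusted p = 0.201). The list was called lower with the block (median −1.11, adjusted p = 0.0456), with the letter (−2.31, adjusted p = 0.00921), in M only (−2.28, adjusted p = 0.0166) and without WT replicate 3 (−0.99, adjusted p = 0.0312), and without JMML replicate 3 the median was −0.47 (adjusted p = 0.432). Trem2 (1.92 ± 0.23) and Cd68 (0.92 ± 0.12) were higher, and Slc40a1, the iron exporter ferroportin, was lower (−1.26 ± 0.18). The 5 lower became 10 with the letter, 9 in M only, and 3 without JMML replicate 2, WT replicate 1 or WT replicate 2. Cd68 was at 0.59 with the length trend removed as fitted. Mast cell and basophil genes gave 5 of 15 lower (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.227), with Prss34 at −1.96 ± 0.21. These 5 became 2 with the block, 3 with the letter, 2 in M only and 2 without WT replicate 1 or WT replicate 2.

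Genes of MHC class II antigen presentation rose together. In this list 9 of 10 members were higher (9 adjusted over the list alone; median 2.27, adjusted p = 4.09e-08 in camera and 0.399 with an estimated correlation). H2-Aa rose from 53.4 ± 12.8 to 523 ± 132 CPM, H2-Ab1 had a fold change of 3.24 ± 0.20, Cd74, the invariant chain, of 2.79 ± 0.20, and Ciita, the master regulator of these genes on another chromosome, of 2.56 ± 0.14. The H2 genes are highly variable between mouse strains. Dendritic cell genes split, with 5 of 14 higher and 4 lower (5 and 4 adjusted over the list alone; median −0.08, between −0.59 and 0.69 over all settings, adjusted p = 0.865). Xcr1, at chromosome 9, 123852315 to 123862029, rose from 1.33 ± 0.453 to 30.3 ± 10.4 CPM. Clec9a, also a marker of cross-presenting dendritic cells, had a fold change of 2.21 ± 0.23, and Itgax (CD11c) of 1.72 ± 0.15, whereas Tcf4, a factor of plasmacytoid dendritic cells, was lower (−1.34 ± 0.12; −0.87 and −0.83 with the length trend removed as fitted and centred). The inflammatory list had 5 of 17 members higher (7 higher and 1 lower adjusted over the list alone; median 0.52, adjusted p = 0.0103 in camera and 0.459 with an estimated correlation), with Nlrp3 at 1.54 ± 0.19 and Tnf at 1.17 ± 0.18; without JMML replicate 1 that call ended (adjusted p = 0.0691). Its 5 higher became 3 with the letter and in M only, and its median 0.33, 0.34 and 0.33 with the letter, in M only and with library totals alone. Interferon genes gave 4 of 20 higher (3 adjusted over the list alone; median 1.48, adjusted p = 0.0111 in camera and 0.851 with an estimated correlation). The mean log2 CPM of the interferon list was 2.53, 4.10 and 5.60 in JMML replicates 1, 2 and 3 and lay between 2.76 and 3.12 in WT, and without JMML replicate 3 the call ended (adjusted p = 0.168, median 0.41). Oas1a, an interferon-induced synthetase, had a fold change of 2.70 ± 0.54, and its call ended without WT replicate 2 (2.70). The 4 higher became 8 with the DESeq2 Wald test, 1 with limma-voom, 11 without the low-count filter, 1 with the block, 17 with the letter and 19 in M only. They became 15, 1 and 2 without JMML replicates 1, 2 and 3, and 1, 0 and 1 without WT replicates 1, 2 and 3, so the number of interferon genes called depends on the setting. The list median became 2.52 with the letter and 2.56 in M only. Trex1 (3.45 ± 0.64), a DNA exonuclease, and Oas1g (3.32 ± 0.54) varied likewise, Trex1 at 1228, 8244 and 8129 counts in JMML replicates 1, 2 and 3.

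Glycolysis genes were higher in all 3 JMML libraries. Of 17 list members, 14 were higher and 1, Hk1, was lower (14 and 1 adjusted over the list alone; median 1.04, adjusted p = 6.76e-08 in camera and 0.459 with an estimated correlation). Eno1 had 608 ± 35.6 CPM in JMML and 241 ± 28.6 in WT, Pgk1 had 388 ± 40.2 and 164 ± 11.2, and the glucose transporter gene Slc2a1 had a fold change of 1.43 ± 0.14. Ddit4, a stress-induced inhibitor of mTOR and a member of the FoxO target list, had a fold change of 3.43 ± 0.48 (2.00 with the letter and 2.04 in M only). Cholesterol synthesis genes gave 5 of 18 higher (6 adjusted over the list alone; median 0.62, adjusted p = 0.00285 in camera and 0.785 with an estimated correlation), with Mvd at 1.45 ± 0.25. These 5 became 2 with library totals alone, 8 with the DESeq2 Wald test, 3 with limma-voom, 8 without the low-count filter, 3 with the strict filter, 14 with the letter and in M only, and 1 without each single WT replicate. The median became 1.13 with the letter, 1.17 in M only and 0.23 without JMML replicate 3.

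Genes of the Ras pathway were examined whatever their values, since JMML often carries changes in them. Nf1, a negative regulator of Ras at chromosome 11, 79339693 to 79581612, had 30.1 ± 2.30 CPM in JMML and 59.7 ± 10.96 in WT (log2 fold change −0.99 ± 0.15, adjusted p = 0.00614). Long transcripts were lower in JMML in general: among 179 genes matched to Nf1 in exon length and level the median was −0.26 and 8.94% were lower than Nf1. Counts over a whole gene do not test for a deleted exon, and the labels name no targeted gene. Ptpn11 (0.05 ± 0.16), Nras (0.14 ± 0.12) and Cbl (−0.06 ± 0.16) did not pass the test. Nf1 stayed called in 21 of 21 alternative settings, and its fold change shrank to −0.63 and −0.60 with the length trend removed as fitted and centred. Of the Ras and PI3K list, 3 of 22 members were higher and 6 lower (3 and 6 adjusted over the list alone; adjusted p = 0.693), with Map2k1 at 1.04 ± 0.13. The 6 lower became 2 without the low-count filter, 3 with the block, 1 with the letter and in M only, 3 without JMML replicate 2, JMML replicate 3 or WT replicate 3, 2 without WT replicate 2, and 3 and 2 with the length trend removed as fitted and centred. The 3 higher became 1 with library totals alone and 5 with the length trend removed in both forms. MAPK feedback genes gave 2 of 21 higher and 6 lower (4 and 7 adjusted over the list alone; adjusted p = 0.72), with Fos at 2.35 ± 0.50 and Myc at −1.02 ± 0.17. Those 6 lower became 1 with the letter and in M only and 3 without JMML replicate 2, JMML replicate 3, WT replicate 1 or WT replicate 2, and the 2 higher became 5 with the DESeq2 Wald test and without the low-count filter. The calls of Fos and Myc ended with the letter (1.19 and −0.96) and in M only (1.23 and −0.92). Receptors for GM-CSF, to which JMML progenitors are known to be sensitive, were higher, Csf2ra by 0.95 ± 0.11 and Csf2rb by 0.87 ± 0.11, whereas the STAT5 target Socs2 was lower (−1.45 ± 0.23), a call that ended with the letter (−1.28) and in M only (−1.24). The GM-CSF list as a whole gave 2 of 17 higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.751). The 3 lower became 1 with the block, 0 with the letter and in M only, and 1 without JMML replicate 1, JMML replicate 2, WT replicate 1 or WT replicate 2. FoxO targets gave 5 of 20 higher and 5 lower (5 and 6 adjusted over the list alone; adjusted p = 0.896). The 5 higher became 3 with the letter and without WT replicate 2.

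**Figure D2:**
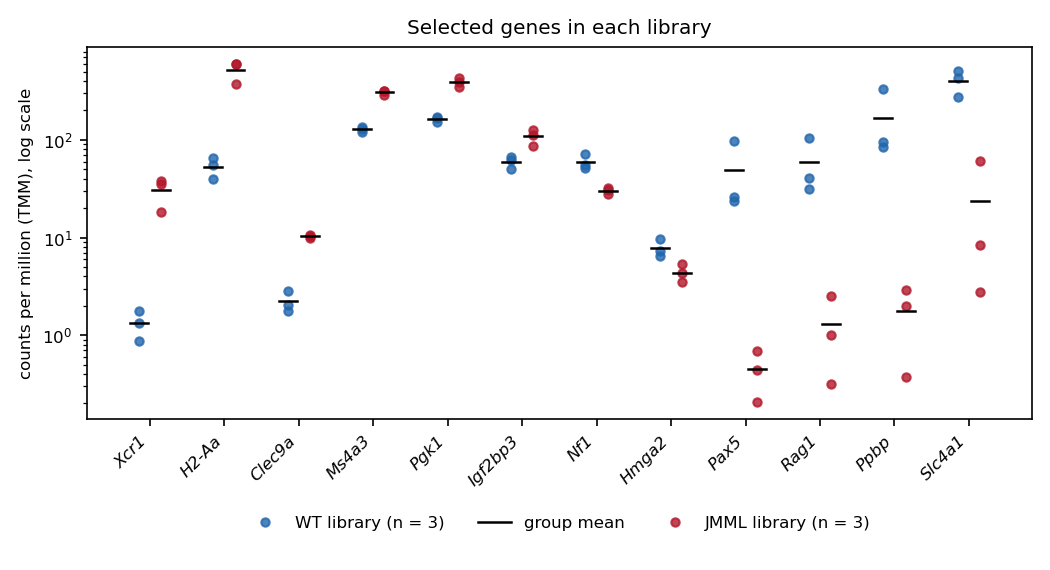
CPM scaled by TMM (y axis, log scale) in each library for 12 genes (x axis) that the naming rule gives; points are libraries, 3 per group, and bars are group means. Xcr1 has a mean of 1.33 in WT and 30.3 in JMML, and Nf1 has 59.7 and 30.1.

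Genes of the fetal Lin28b axis, which the series title makes of interest, did not move as one. Of 10 tested members 4 were higher and 2 lower (4 and 3 adjusted over the list alone; median 0.01, between −0.83 and 0.51 over all settings, mean −0.23, adjusted p = 0.72 in camera in the upward direction). The 4 higher became 2 with the letter and without WT replicate 1 or WT replicate 2. Igf2bp3, a fetal RNA-binding protein at chromosome 6, 49085223 to 49214957, had 108.4 ± 19.7 CPM in JMML and 59.7 ± 8.88 in WT (0.86 ± 0.17, adjusted p = 0.0124). Hmga1 (0.57 ± 0.10), Arid3a (0.77 ± 0.16) and Lin28a (0.97 ± 0.24, outside the naming rule) were higher, and Mycn (−1.57 ± 0.31) and Hmga2 (−0.83 ± 0.24, adjusted p = 0.042) were lower. Of 21 alternative settings the call held in 20 for Igf2bp3, 19 for Arid3a, 19 for Mycn, 17 for Hmga1 and 9 for Hmga2. It ended with the letter for Igf2bp3 (0.91), with the letter and in M only for Mycn (−1.55 and −1.51) and Hmga1 (0.44 and 0.48), and without WT replicate 1 (0.75) or WT replicate 2 (0.69) for Arid3a. With the length trend removed as fitted and centred Hmga1 lost its call as well, at 0.31 and 0.34. Hmga2 lost its call without the low-count filter, with the block, with the letter, in M only, after thinning, with the length trend removed in both forms, and without any single replicate but JMML replicate 2, at fold changes of −0.66 to −0.90. Lin28b itself had 1.77 ± 0.551 CPM in JMML and 1.09 ± 0.255 in WT, and did not pass the test (0.70 ± 0.35, adjusted p = 0.173). The embryonic globin genes were not testable, as Hbb-y had 0 counts in every library and Hbb-bh1 had 2 counts in WT replicate 3 and 0 elsewhere. Igf2bp1 had between 0 and 35 counts and was not tested. Imprinted growth genes gave 4 of 14 lower (5 adjusted over the list alone; median −0.95, adjusted p = 0.0662), among them Grb10 (−1.06 ± 0.17) and Mest (−1.99 ± 0.59). These 4 became 2 with the block, with the letter, in M only and without WT replicate 2 or WT replicate 3. The list was nevertheless called lower with the block (adjusted p = 0.042), with the letter (median −1.33, adjusted p = 0.0153), in M only (−1.53, adjusted p = 0.019), with protein-coding genes only (adjusted p = 0.0221), without WT replicate 1 (adjusted p = 0.00215) and after thinning to equal totals (adjusted p = 0.047), while without WT replicate 3 the median was −0.52 (adjusted p = 0.339). Grb10 lost its call with the letter (−0.88) and in M only (−0.85). Mest lost its call with the block and without JMML replicate 1 or any single WT replicate, and was at −3.73 with the letter and −3.69 in M only.

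Proliferation lists gave no call in the main test. Of 20 mitotic genes 1 was higher and 2 lower (0 in either direction adjusted over the list alone; adjusted p = 0.523), with Mki67 at −0.45 ± 0.13, and of 20 replication genes 1, Cdc6, was lower (−0.71 ± 0.18; 0 adjusted over the list alone; adjusted p = 0.268). The 2 lower mitotic genes became 0 without the low-count filter, with the block, with the letter, in M only, without any single replicate and with the length trend removed in both forms, and the 1 lower replication gene became 4 with library totals alone. Mki67 lost its call wherever those 2 did, at −0.23 and −0.20 with the length trend removed as fitted and centred. Cdc6 lost its call with the block, with the letter (−0.41), in M only (−0.38) and without any single replicate but JMML replicate 3. The mitotic list (median 0.10, between −0.08 and 0.36 over all settings) was called higher without the low-count filter (0.19, adjusted p = 0.0149), with the letter (0.33, adjusted p = 0.0153) and in M only (0.36, adjusted p = 0.00453), and the replication list was called lower without JMML replicate 3 (adjusted p = 0.0405). Targets of p53 gave 3 of 16 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.368), with Pmaip1, a promoter of cell death, at 1.40 ± 0.20, and the list was called higher without the low-count filter (adjusted p = 0.0227). Of the osteoblast and cartilage list 3 of 14 were higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.694; median −0.38, between −0.84 and 0.65 over all settings, mean 0.13). The 3 higher became 5 without the low-count filter, 1 with the block, 0 with the letter and in M only, 1, 1 and 5 without JMML replicates 1, 2 and 3, and 1, 0 and 5 without WT replicates 1, 2 and 3. The 1 lower was Runx2, an osteoblast transcription factor (−1.02 ± 0.15), called in 21 of 21 alternative settings. The 3 higher were the bone-resorption protease gene Ctsk (1.96 ± 0.42), Spp1 (2.51 ± 0.63) and Acp5 (0.99 ± 0.27). The call of Ctsk ended with the letter (1.45), in M only (1.49) and without WT replicate 2 (1.75). Those of Spp1 and Acp5 ended with the block, with the letter (0.79 and 0.48) and in M only (0.83 and 0.51). They also ended without JMML replicate 1 or 2 or WT replicate 1 or 2, and that of Acp5 with the length trend removed in both forms. None of 4 tested hepatocyte genes was called (0 adjusted over the list alone; adjusted p = 0.89).

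Features of RNA and library make-up also differed between the groups. Immediate early and stress genes, which respond to tissue handling, gave 7 of 15 higher and 1 lower (9 and 1 adjusted over the list alone; median 1.24, adjusted p = 0.00102 in camera and 0.459 with an estimated correlation), with Junb at 1.38 ± 0.22 and Hspa1a at 2.15 ± 0.34. The 7 higher became 4 in M only, and the median became 0.81 with the letter; Junb was at 0.81 with the letter and 0.84 in M only. Among 10305 protein-coding genes the fold change fell with exon length (Spearman rho −0.33 across genes, which are not independent replicates), from a median of 0.36 in the shortest decile to −0.19 in the longest. Of 774 sense-intronic and TEC loci, short unconfirmed transcripts mostly inside other genes, 260 were lower and 3 higher. Histone genes gave 0 of 15 called members (0 adjusted over the list alone) although the list was called higher (median 0.33, adjusted p = 0.0303 in camera and 0.836 with an estimated correlation). That call ended with the strict low-count filter (adjusted p = 0.0759), without JMML replicate 3 (adjusted p = 0.142) or WT replicate 2 (median 0.14, adjusted p = 0.203), and with the length trend removed, where the direction turned (median −0.081 as fitted and −0.053 centred). The median became 0.15 with library totals alone, 0.58 with the letter, 0.62 in M only and 0.68 without WT replicate 1, where 4 histone genes were higher. Mitochondrial genes gave 1 of 13 lower (0 adjusted over the list alone; adjusted p = 0.869), small structured RNAs 1 of 13 lower (0 adjusted over the list alone; adjusted p = 0.368), and the sex-linked list 1 of 5 higher, Xist (1 adjusted over the list alone; adjusted p = 0.057). The mitochondrial 1 lower became 3 with library totals alone, and 4 and 3 with the length trend removed as fitted and centred, and the sex-linked 0 lower became 4 with limma-voom and without JMML replicate 3. The small structured RNA list was called higher without the low-count filter (adjusted p = 0.0219). The sex-linked list was called lower without the low-count filter, with the strict filter, with protein-coding genes only, after thinning and without JMML replicate 3, WT replicate 2 or WT replicate 3 (adjusted p between 0.00583 and 0.0470). The call of Xist ended with limma-voom (6.56), with the block, with the letter (−2.87), in M only (−2.87) and without JMML replicate 2 or any single WT replicate.

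**Figure D3:**
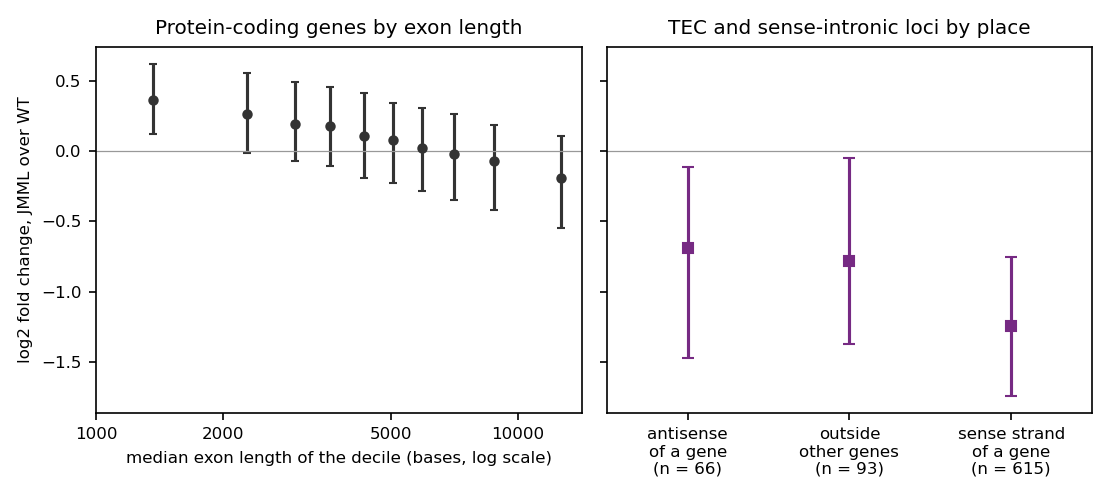
Log2 fold change (JMML over WT, y axis) as median and quartiles, left for deciles of protein-coding genes by exon length (x axis, bases, log scale) and right for TEC and sense-intronic loci by their place relative to other genes. The decile medians run from 0.36 to −0.19, and the loci in the sense strand of another gene have a median of −1.25.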

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

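Thinning to equal totals and both forms of length correction were chosen after seeing the data, the centred form after the values of the other. With library totals alone 1280 genes were higher. Deviations of same-numbered libraries from their group means correlated at −0.20, 0.05 and −0.14, against −0.10 to 0.23 for other pairs, which shows no sign of pairing by number. Deviations from a mean of 3 libraries constrain one another, so these values cannot exclude pairing, such as between JMML replicate 3 and WT replicate 3. With the number as a replicate block 1358 genes were higher, 1451 lower and 2809 changed in total. With the identifier letter as a covariate the counts were 969, 1250 and 2219, and in the libraries with the letter M, where 1 JMML library is assumed to vary like the WT libraries, 1012, 1298 and 2310. Of the 4737 called genes, 1800 were called in the same direction with the letter as a covariate, and 39.5% with the letter M alone, 57.2% with the block, 94.4% after thinning, and 79.6% and 80.2% with the length trend removed as fitted and centred. The block, covariate and M fits leave fewer samples or residual degrees of freedom. In the covariate fit, as in the M fit, the group difference rests on JMML replicate 3 against WT. The cause of the lower counts was not tested further. Leaving out 1 replicate gave 1050 to 1955 genes higher, 1153 to 2048 lower, 2203 to 4003 in total and 1438 to 2320 changed by at least 2-fold, and 16 to 19 lists, with each list call that ended or was gained named in the report. The lowest counts of genes were without WT replicate 2, which moved all 4 counts by over 1.5 times; the lower count also moved so far without JMML replicate 2 (1515) or 3 (1622) and WT replicate 1 (1628) or 3 (1659), and the total without JMML replicate 2 (3043) or WT replicate 1 (3136). A test against a 1.5-fold change called 1346 genes, where the 2-fold criterion gave 2491. Camera with an estimated correlation called 0 lists and fry 12, against 17. The histone list reversed with the length trend removed, to −0.081 as fitted and −0.053 centred, and Xist reversed to −2.87 with the letter as a covariate and −2.87 with the letter M alone, as the 2 libraries with high Xist are those with F; the cause was not tested for the histones. Of 139 called named genes, 39 lost the call with the letter as a covariate while their direction held, and Xist lost it with its direction reversed. Without WT replicate 2, 36 lost the call. The other scalings, tests, filters and gene sets kept each count within 1.5 times.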

Other observations

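The tests of the length trend, of the equal dilution and of thinning were chosen after the result was seen; the other bounds were set after the pattern was noticed and before the value they concern was computed.

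Markers of cross-presenting dendritic cells (cDC1) rose, while the dendritic list as a whole went both ways. Xcr1, Clec9a and Batf3 were higher in JMML, and Cd209a was lower, at 0.0293 ± 0.0508 CPM in JMML and 8.35 ± 2.05 in WT (SD, n = 3); Batf3 and Cd209a were chosen after their values were seen. A candidate explanation is a larger share of cDC1-like transcripts. In 9 further cDC1 genes, listed before their values were looked at, 6 were higher and 0 lower, with a median log2 fold change of 1.68 (adjusted p = 0.000181 in camera over 3 such lists, and adjusted p = 0.0672 with an estimated correlation). Id2 (4.54-fold) and Rab7b (4.89-fold) were among the 6, and Cd24a was not called (−0.43 ± 0.24). Of 6 further cDC2 genes 2 were higher and 0 lower (median 0.43, adjusted p = 0.376 in camera). The values go with the hypothesis, but leukemic cells that express these genes and a larger number of dendritic cells were not told apart, and no cell was counted.

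Genes of several blood lineages were lower in JMML. The calls did not rest on unequal depth, since 62 of 69 members of the B-cell, megakaryocyte, erythroid and T-cell lists were lower after thinning to equal totals. All 61 from before were among them. Values were already scaled by library size and the JMML libraries were the deeper ones, so thinning could hardly have ended falls this large. One equal dilution by other cells is argued against by the lists' sizes. The B-cell median lay below the T-cell median by a difference of −2.74 (95% bootstrap interval over list members −4.08 to −1.24). The natural killer median was 0.07. The interval resamples genes and does not measure the spread between libraries. By library, the mean log2 CPM of the B-cell list was −0.51 to 0.92 in JMML and 3.65 to 5.58 in WT. That of the T-cell list was 0.55 to 1.19 in JMML and 2.06 to 3.01 in WT. Without WT replicate 3 the B-cell and T-cell medians were −3.40 and −1.88. A loss that differs between lineages, which the leukemia label makes a biological hypothesis, stays open, as do differences in the tissue part or age sampled, which the labels do not give. In each WT library the B-cell and megakaryocyte means lay above every JMML library.

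Sense-intronic and TEC loci were lower in JMML. Most of the calls did not rest on unequal depth, as 253 loci were lower after thinning to equal totals, and 233 of the 260 were among them. Loci in the sense strand of 1 tested protein-coding gene lay below that gene by a median of −1.06. The interval was −1.11 to −0.99 over 564 loci, which share 372 genes and are not independent. This goes with a larger unspliced share in WT, but genomic DNA in WT would also lower such loci against their genes. Genomic DNA in the WT libraries is not excluded: loci outside every other gene were also lower (median −0.78), and the difference of −0.47 between sense and outside loci lay inside the bound of 0.5 set for that cause, although its interval (−0.87 to −0.26) reaches past the bound and leaves out 0. These loci took 0.0565% to 0.0804% of counts in JMML and 0.126% to 0.224% in WT. The pattern was not limited to them: lincRNA, antisense and processed-transcript genes had medians of −0.38, −0.34 and −0.35. Protein-coding genes had a median of 0.005 and processed pseudogenes of 0.27. Genes with a count numbered 24038 ± 1552 in JMML and 27099 ± 3089 in the shallower WT libraries (SD, n = 3).

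The glycolysis list was higher in JMML. With the length trend removed its median was 1.01 (log2), and over the scalings run it was at least 0.86. The test could hardly have ended otherwise. Library totals alone moved the median of all genes by −0.18, and the shortest length decile had a median of 0.36. Neither could bring the list's median of 1.04 under the bound of 0.5. The medians show only that the scalings run and the fitted length trend are smaller than the shift of the list. The camera call held in each as well. Camera compares list members with all other genes, so a change of scaling could hardly end its call. A hypoxia response could account for part: of 20 HIF target genes outside the list, 6 were higher and 1 lower, with a median of 0.34 (adjusted p = 0.0105 in camera and 0.0672 with an estimated correlation). That median falls between the bounds of 0.5 and 0.25 set for and against this explanation, so a hypoxia response cannot be told apart from a glycolysis change of another origin. The stress and immediate early genes that rose with the same group keep handling time open as well, which was not tested.

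Whether other groupings give as many calls was examined over the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. For genes higher, 1 split, the real one, reached 2245, and the highest other gave 2. For genes lower, 1 split reached 2492, with 2 as the highest other. For all changed genes 1 split reached 4737, and for changes of at least 2-fold 1 split reached 2491, with 4 as the highest other for both. For gene lists 4 splits reached the real value of 17, and the highest other gave 20. The 3 other splits, with 18, 20 and 19 lists, are those that keep JMML replicates 1 and 2, the libraries with the letter F, on one side. With the letter as a covariate camera called 20 lists for the group. Camera with a preset correlation thus calls many lists for groupings in which at most 4 genes pass. Every other split mixes the groups unevenly, so part of the group difference stays in it. The list calls there may reflect that part, the letter or correlated genes within lists, which were not tested apart. The rest of the group difference adds to the spread within each side of such a split. Few gene calls were therefore likely there, whatever the cause of the group difference. The gene counts of the splits thus do not weigh chance, the letter or another cause. The list calls carry less weight than the calls of single genes because none was called with an estimated correlation.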
